A study of Homo sapiens with 2 samples.

How the data were processed

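Per the labels' protocols, human bone marrow from a donor was thawed, sorted by flow cytometry for live ILC1s or live NK cells, made into Chromium 10x libraries and sequenced on a HiSeq2500. Per the submitters' processing notes, Cell Ranger 1.2 and Seurat were used with genome hg38; the order and settings of their steps, and the sort gates, are not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode, whole numbers without normalization, over 33694 genes with Ensembl identifiers and symbols. Each sorted population is 1 sample, so 2 libraries were compared with 1 library per group.

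Everything else was computed from those counts. Barcodes with at least 200 detected genes and under 10% mitochondrial UMIs were kept, which left out 23 ILC1-library barcodes (3 for genes, 20 for mitochondrial UMIs) and 41 NK-library barcodes (4 and 37). Sex-linked genes (109) were left out of all profiles. The filtered cells held 4745644 UMIs in the ILC1 library (quartiles per cell 2542 and 4738.5, median mitochondrial share 3.09%) and 2868526 in the NK library (2767.5 and 3688.5, 3.90%).

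Counts were summed over the cells of a library or class and divided by their total to give CPM. Ratios are ILC1 over NK, with exact Poisson intervals for a sum and exact conditional binomial intervals for a ratio. With 1 library per group there was no test, p-value or standard error, and cells were not used as replicates. Genes counted as higher at 2-fold with at least 20 CPM in the higher library. For ranking, for list medians and for a gene with 0 counts, a count under 3 was set to a floor of 3 counts over the group; a ratio against 1 or 2 counts is printed from the counts as they stand, with its interval. TMM factors from edgeR were an alternative scaling. Log ratios of whole libraries include the differences in cell composition.

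Gene lists (25, with 409 genes, all found in the files) were written before the data were examined: NK cytotoxic effector, CD56-bright-type NK, helper ILC, ILC2, ILC3, T cell, naive and memory lymphocyte, IMiD target, cytokine and chemokine, cytokine and chemokine receptor, transcription factor, NK receptor, immediate-early and heat shock, interferon response, proliferation, cytoskeleton and adhesion, MHC class II presentation, B lineage, plasma cell, monocyte, granulocyte precursor, erythroid, HSPC, dendritic, and platelet and megakaryocyte. Members with at least 5 CPM in either library were measured, and a member counted as higher or lower when it was at least 1.5-fold apart and the interval of its ratio excluded 1. A list's median was placed among 10000 random lists of equal size, drawn to match on mean expression in 20 bins, as a description of these libraries. Lists share some members, for example IL7R, XCL2 and TBX21.

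The rule for named genes was fixed at the same time: among genes with at least 50 CPM in the higher library the 15 with the largest ratio in each direction; for each list the 3 members with the highest mean CPM and the member with the largest ratio in each direction, at most 5; and 23 genes or complexes for shares of cells. XIST, TSIX and Y-linked genes were left out everywhere; ribosomal protein, mitochondrial, immunoglobulin and T cell receptor variable, diversity and joining genes, clone-named transcripts and genes whose presence varies between people were left out of the naming by size, and 1 further gene of variable copy number is not listed. The rule named 135 genes, and some results are not reported. Other list members in the text (such as RUNX3, IRF4 and GATA3) and all genes of the class comparisons were chosen after their values were seen. Gene positions come from GENCODE 29 on GRCh38, matched by Ensembl identifier.

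Cells of both libraries were clustered together after log normalization to 10000 counts, with 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.6, giving 11 clusters. A cluster took the name of the type with the largest part of its fixed markers enriched at least 2-fold and detected in at least 10% of its cells, with at least 3 markers and at least 25% of that type's markers. The 25% minimum was set after the clusters were seen, and no class share of the joint clustering changed without it. A cluster of 66 ILC1-library cells (5.81%) and 0 NK-library cells stayed unnamed because 2 of the 8 markers of its nearest type, dendritic, were enriched, under the minimum of 3. The marker types were T, NK, helper ILC, B, plasma cell, monocyte, granulocyte precursor, erythroid, HSPC, dendritic, and platelet and megakaryocyte, and 10 clusters were named; no cluster was named plasma cell, granulocyte precursor, HSPC or platelet. Scrublet called 1 of 1135 and 61 of 831 cells doublets, 59 of them in the larger NK-like cluster; called cells were kept, and their removal was an alternative. Clusters of high depth were the erythroid-like cluster (median 14617 UMIs in the ILC1 library) and a dendritic-like cluster (10768 UMIs), with 0 called doublets each in that library. Shares with a UMI were taken after thinning each cell to 2000 UMIs, the largest of 500, 1000, 1500 and 2000 that kept at least 80% of cells in both libraries, which left out 176 and 95 cells. Class comparisons used 50 CPM as the minimum.

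The calculation of the ratio and list steps was checked on simulated counts. They were drawn with Poisson error, which the intervals assume, from the mean profile of the 2 libraries. Differences between cells, in composition and from free RNA were not simulated, so the check does not cover them. Of 4710 simulated genes, 200 were changed; all 67 at 3-fold and all 66 at 4-fold passed the 2-fold threshold (100%), against 0% of 67 at 1.5-fold and 0% of 4510 unchanged genes, and 95.4% of intervals held the true ratio. The list step was run on 9202 simulated genes. Of 100 unchanged lists of 20 genes, 94 fell inside the middle 95% of random lists, and a list of raised genes fell at percentile 100.

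Alternatives fixed in advance were all barcodes, a stricter cell filter (500 genes, 5% mitochondrial), other scalings, per-cell means, doublet removal, removal of other-lineage and T-like clusters, other CPM minimums and folds, other thinning and other clustering settings. Added after seeing the data were removal of the 3 immunoglobulin-rich cells, NK-like, T-like and helper ILC-like cells only, NK-like cells only, and naming without the 25% minimum. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.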

Results

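Droplet-based single-cell RNA sequencing (10x Genomics Chromium) was carried out on human bone marrow cells that had been thawed and sorted by flow cytometry into 2 populations, type 1 innate lymphoid cells (ILC1s) and natural killer (NK) cells. ILCs are lymphocytes without rearranged antigen receptors. ILC1s and NK cells both depend on T-box transcription factors. NK cells are the cytotoxic members of the family, and the helper ILCs comprise ILC1s, ILC2s and ILC3s. The series was set in work on marrow ILC subsets as targets of immunomodulatory imide drugs (IMiDs), which bind cereblon (CRBN) and lead to degradation of the Ikaros-family factors IKZF1 and IKZF3. Each population was represented by 1 library, so no difference had a replicate check and the values describe these libraries. The ILC1 library held 1158 barcodes and 4795768 unique molecular identifiers (UMIs), and the NK library 872 barcodes and 2944361 UMIs. After filtering, 1135 cells with a median of 3527 UMIs and 1129 detected genes remained in the ILC1 library, and 831 cells with a median of 3256 UMIs and 1263 genes in the NK library. Ribosomal protein genes took 33.7% of UMIs in the ILC1 library and 26.2% in the NK library. All intervals are 95% intervals and cover counting error only.

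The first comparison asked which cell classes each sorted population contained. The library of sorted ILC1s held lymphoid and myeloid classes side by side, whereas the library of sorted NK cells was mostly NK-like. Monocyte-like cells made up 40.4% of the ILC1 library (458 cells, exact binomial interval 37.5 to 43.3%) and 0.241% of the NK library (2 cells, 0.0292 to 0.867%). T-like cells were 23.8% of the ILC1 library (270 cells, 21.3 to 26.4%) and helper ILC-like cells 13.2% (150 cells, 11.3 to 15.3%). Both were at 0 of 831 cells in the NK library, which allows a share of up to 0.361%. NK-like cells were 96.3% of the NK library (800 cells, 94.7 to 97.5%) and 3.70% of the ILC1 library (42 cells, 2.68 to 4.97%). B-like cells were 4.93% of the ILC1 library (56 cells) and 0 of 831 cells in the NK library.

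Smaller classes were present in both libraries. Dendritic-like cells were 5.81% of the ILC1 library (4.53 to 7.34%) and 2.05% of the NK library (1.196 to 3.26%). They fell into 2 clusters, one with 35 ILC1-library and 17 NK-library cells and one with 31 and 0. Erythroid-like cells 2.38% (1.57 to 3.44%) and 1.44% (0.748 to 2.51%). A cluster of 66 cells, 5.81% of the ILC1 library, carried too few fixed markers of any type and stayed unnamed. It held 0 of the 831 NK-library cells. MS4A7, a member of the monocyte list, was its most enriched gene. After thinning, LYZ was detected in 73.3% and S100A9 in 85.0% of its cells. In the same library, monocyte-like cells stood at 100 and 99.7%, and dendritic-like cells at 58.5% for both genes. FCGR3A was detected in 85.0% of the unnamed cells and NKG7 in 11.7%, against 2.16 and 8.09% of monocyte-like cells. Whether the unnamed cells are monocytes was not tested. The monocyte-like share leaves them out and is too low if they are monocytes. Results without other-lineage clusters keep them. Cells outside the T-like, NK-like and helper ILC-like classes were 59.3% of the ILC1 library (56.4 to 62.2%) and 3.73% of the NK library (2.55 to 5.25%). The sort gates can set all of these shares. A cluster drawn from 1 library, such as the T-like and helper ILC-like clusters here, may owe its separation from cells of the other library to the library. Library alone does not separate these 2 clusters from each other, since both come from the ILC1 library. With each library clustered alone, NK-like cells fell to 44.0% of the NK library because 51.6% of its cells were left unnamed. The naming rule asks for markers 2-fold over the other clustered cells, and in this library those are mostly NK-like. The fall therefore does not speak against NK-like cells, and NKG7 was detected in 97.4% of all thinned NK-library cells.

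**Figure D1:**
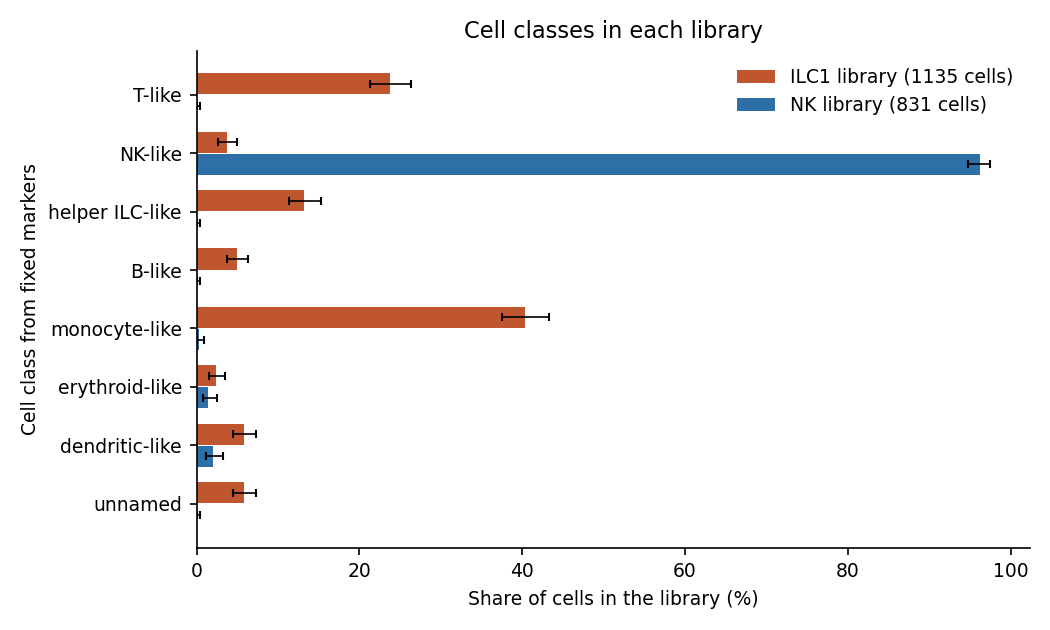
Share of cells in each class named from fixed markers, as a percent of the filtered cells of the ILC1 library (1135 cells, orange bars) and the NK library (831 cells, blue bars). Error bars are exact 95% binomial intervals; monocyte-like cells stand at 40.4% in the ILC1 library, and NK-like cells at 96.3% in the NK library and 3.70% in the ILC1 library.

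The second comparison asked which genes differed between the libraries as a whole, with UMI counts summed over all filtered cells and given as CPM, which scales every library to an equal total. Genes of monocytes and of antibodies led the ILC1 library, and genes of cytotoxic NK cells led the NK library. S100A8 and S100A9, calcium-binding proteins abundant in monocytes and neutrophils, stood at 10220 against 19.9 CPM (log2 ratio of ILC1 over NK 9.01, interval 8.63 to 9.41) and at a log2 ratio of 7.89 (7.63 to 8.16). GNLY, which encodes the granule protein granulysin, stood at 233 against 7163 CPM (log2 −4.94, −5.03 to −4.86), and NKG7, a granule membrane protein of cytotoxic lymphocytes, at 394 against 7257 CPM (log2 −4.20, −4.27 to −4.13). IL7R, the interleukin-7 receptor chain found on helper ILCs and T cells, was higher in the ILC1 library, at 217 against 10.1 CPM (log2 4.43, 3.90 to 5.01). On GRCh38 with GENCODE 29 annotation, S100A8 (ENSG00000143546) is a protein-coding gene on chromosome 1 from 153390032 to 153391188. GNLY (ENSG00000115523) lies on chromosome 2 from 85685175 to 85698854. NKG7 (ENSG00000105374) lies on chromosome 19 from 51371606 to 51372715. IL7R (ENSG00000168685) lies on chromosome 5 from 35852695 to 35879603.

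Among the 15 genes with the largest ratio toward the ILC1 library were further monocyte genes: S100A12 (5197 against 2 UMIs, log2 10.62, 8.76 to 13.66), the lipopolysaccharide co-receptor CD14 (2213 against 2 UMIs, log2 9.39, 7.53 to 12.43) and the matrix proteoglycan VCAN (log2 7.18, 6.20 to 8.40). They also included the lectin FCN1 (log2 7.06, 6.44 to 7.75), SERPINA1, RBP7 (618 against 0 UMIs, at least 125-fold) and TMEM176B (516 against 0 UMIs, at least 104-fold). The other members included IGKC (33944 against 2 UMIs, log2 13.32, 11.47 to 16.37) and IGHA2 (9204 against 3 UMIs, log2 10.86, 9.31 to 13.13). IGHG1 (8439 against 0 UMIs) was 1700-fold higher at the floor, with a log2 lower bound of 10.43. IGHG2 (1174 against 0 UMIs) was 237-fold higher at the floor, with a log2 lower bound of 7.59. The last were IGLC2 (536 against 1 UMI, log2 8.34, 5.86 to 13.65) and JCHAIN, the joining chain of secreted antibodies (607 against 1 UMI, log2 8.52, 6.04 to 13.83). In the ILC1 library, 3 cells with over 20% of UMIs from immunoglobulin genes held 92.0% of IGKC, 92.7% of IGHA2, 96.8% of IGHG1 and 96.9% of IGHG2 UMIs, but 17.8% of JCHAIN and 0.187% of IGLC2 UMIs. Without these cells, and with the floor of 3 counts, the log2 ratios were 9.12 for IGKC, 7.10 for IGHA2, 5.80 for IGHG1 and 2.88 for IGHG2. IGLC2 was the most enriched gene of the B-like cluster, and JCHAIN was among the 10 most enriched genes of a dendritic-like cluster. Immunoglobulin constant genes resemble each other closely, so UMIs of IGHA2, IGHG1 and IGHG2 may be assigned among near-identical copies.

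Toward the NK library, the largest ratios belonged to the activating receptor NCR1 (log2 −5.14, −6.37 to −4.12), the protease PRSS23 (−5.05, −5.64 to −4.51) and GNLY. They were followed by B3GNT7 (−4.84), FGFBP2 (−4.72, 62.8 against 1660 CPM), MYOM2 (−4.70), FCRL6 (−4.61), the chemokine XCL2 (−4.60) and the interleukin-2 and interleukin-15 receptor chain IL2RB (−4.59, −4.95 to −4.25). Next were ADGRG1 (−4.56), the inhibitory receptor KLRC1 (−4.52), SH2D1B (−4.52), SPON2 (−4.49) and S100B (−4.45). The remaining gene of these 15 is not listed because its copy number varies between people. XCL2 and KLRC1 have close paralogs, so their counts are uncertain to that extent.

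Of 18209 genes with a UMI, 5409 reached 20 CPM in the higher library. Of these, 494 were at least 2-fold higher in the ILC1 library and 873 in the NK library, without a test. The interval lay wholly past 2-fold for 375 and 484 of these genes, and 26 of the genes higher in the ILC1 library had 0 UMIs in the NK library. The higher-in-ILC1 share of the 2-fold genes was 36.1%, against 57.3% with TMM scaling (679 against 506 genes) and 48.8% with totals that left out ribosomal protein and mitochondrial genes (759 against 797 genes). The median log2 ratio of all genes at the minimum was −0.29, and these scalings raised it by 0.28 and 0.15, so ratios of this size have no fixed sign.

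Gene lists fixed in advance showed how the groups differed. Of 28 measured NK cytotoxic effector genes, 24 were higher in the NK library, 1 in the ILC1 library and 3 neither, with a median log2 ratio of −3.83 (−3.91 to −3.60) that lay at percentile 0 of 10000 matched random lists. Its members included the pore-forming protein PRF1 (−3.93), the granzyme GZMB (−3.04), the receptors KLRD1 (−4.04) and KLRF1 (−4.25) and the T-box factors TBX21 (−4.00) and EOMES (−2.67). The exception was GZMK (0.59, 0.35 to 0.83), which turned to −1.61 without the T-like and other-lineage clusters. SRGN, TYROBP and FCER1G, which myeloid cells also express, were near equal. Of 21 NK receptor genes, 17 were higher in the NK library and 1 in the ILC1 library (LILRB1, 0.71, also a receptor of monocytes), with a median of −2.74 at percentile 0. Of 13 CD56-bright-type NK genes, 5 were higher in the ILC1 library, among them IL7R and CD27 (1.60, but −2.32 without the T-like and other-lineage clusters), and 6 in the NK library, among them XCL2 and IL2RB. The median was −0.24 at percentile 45.6 and 0.04 with TMM scaling. Restricted to NK-like cells of both libraries, the median log2 ratio of the NK cytotoxic effector list was 0.0865.

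The helper ILC list went both ways. Of 20 measured members, 10 were higher in the ILC1 library, among them IL7R, the lymphotoxin chain LTB (2.82), IL23R (29 against 0 UMIs), AHR (3.34) and GATA3 (0.86). The NK library was higher for 9, among them ID2 (−0.99), RORA (−0.75) and ZBTB16 (−1.12). The median was 0.61 at percentile 99.96. ILC2 genes had 5 of 9 members higher in the ILC1 library and 3 in the NK library, with a median of 0.86 at percentile 99.88. The prostaglandin D synthase HPGDS had 197 against 0 UMIs (at least 39.7-fold) and the prostaglandin D2 receptor PTGDR2 had 60 against 0 UMIs. ILC3 genes had 5 of 6 members higher in the ILC1 library, including the chemokine CXCL8 (183 against 1 UMI), which monocytes also make, and 1 in the NK library (NCR3, −2.06), with a median of 2.50 at percentile 99.94. The helper ILC and ILC2 medians turned to −0.17 and −0.41 when every member with a UMI counted. A member under 3 counts in both libraries takes a negative ratio from the floor there, since the ILC1 library holds more UMIs. No change of direction is read from these 2 values.

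Of 21 T cell genes, 11 were higher in the ILC1 library and 8 in the NK library, with a median of 1.75 at percentile 100. The CD3 subunits CD3D (4.23), CD3G (3.15) and CD3E (2.48), TRAC, CD4 (4.75, a gene that monocytes also express) and CD40LG (109 against 0 UMIs) were on the ILC1 side. On the NK side were TRDC (−2.68), TRBC1 (−2.12), CD2 (−1.71) and LAT (−1.35). UMIs of TRBC1 may be shared with its near copy TRBC2. Members at 20 CPM or more had a median of −0.76, and without the T-like and other-lineage clusters the median was −0.82. Of 14 naive and memory lymphocyte genes, 5 were higher in the ILC1 library and 3 in the NK library (median 0.39, percentile 99.74; −0.20 without those clusters).

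Markers of other lineages, measured because a sort may admit them, were mostly higher in the ILC1 library. All 15 monocyte genes (median 5.90, percentile 100), all 14 B lineage genes (3.89, percentile 100) and all 6 granulocyte precursor genes (4.61, percentile 100) were higher there. So were all 8 MHC class II presentation genes (1.74, percentile 99.99), all 5 platelet and megakaryocyte genes (2.64, percentile 99.7), 14 of 15 dendritic genes (2.48, percentile 100), 7 of 9 hematopoietic stem and progenitor cell (HSPC) genes (2.27, percentile 99.96) and 7 of 11 plasma cell genes (3.05, percentile 100). Erythroid genes were the exception, with 12 of 15 higher in the NK library and 1 in the ILC1 library (median −1.33, percentile 0). HBB, the beta-globin gene, stood at 2874 against 6026 CPM (log2 −1.07). Erythroid-like cells ran the other way, with 9.87% of UMIs in the ILC1 library and 5.88% in the NK library. HBB was also detected in 38.9% of NK-like cells of the NK library and 22.4% of monocyte-like cells of the ILC1 library after thinning to 2000 UMIs. Restricted to T-like, NK-like and helper ILC-like cells, the MHC class II median was −0.58 and the dendritic median −0.64, and without the other-lineage and T-like clusters the plasma cell median was −0.93.

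Cytokine and chemokine genes were higher in the NK library for 10 of 15 members, such as CCL5 (−2.46), CCL4 (−3.81) and XCL2. The ILC1 library was higher for 4, LTB, CXCL8, CSF1 (24 against 1 UMI) and TNFSF10 (1.46), and the median was −1.08 at percentile 0.08. Cytokine and chemokine receptor genes were higher in the NK library for 11 of 20 members and in the ILC1 library for 6, including IL7R, IL2RA (53 against 0 UMIs) and CCR6 (2.27), with a median of −0.99 at percentile 0. Transcription factor genes were higher in the NK library for 13 of 27 members, such as TBX21, RUNX3 (−3.01), HOPX (−2.86) and EOMES, and in the ILC1 library for 4, among them IRF8 (1.43), MAF (0.89) and GATA3 (median −0.58, percentile 2.65). In NK-like cells only, the 3 medians were 0.18 for the cytokine and chemokine list, 0.34 for their receptors and 0.0532 for the median log2 ratio of the transcription factor list, but the floor of 3 counts lifts low members there. With members at 50 CPM in the same cells they were 0.04, 0.12 and −0.15, so the transcription factor median has no fixed sign. IRF8 turned to −1.32 without the other-lineage clusters, a population that keeps the unnamed cluster, and to −2.48 among T-like, NK-like and helper ILC-like cells alone, where RORA stood on the ILC1 side at 0.61.

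Immediate-early and heat shock genes were higher in the ILC1 library for 11 of 24 members, such as FOS (3.08) and DUSP1 (1.78), and in the NK library for 1, DNAJB1 (−0.74), with a median of 0.21 at percentile 99.8. Interferon response genes were split, with 7 of 23 higher in the ILC1 library, such as OAS1 (1.72), and 8 in the NK library, such as IFITM1 (−2.80), and a median of 0.19 (percentile 99.52). Proliferation genes were higher in the ILC1 library for 12 of 24 members and in the NK library for 0 (median 0.65, percentile 100); without other-lineage clusters their median was −0.48. Cytoskeleton and adhesion genes were higher in the ILC1 library for 10 of 27, such as S100A11 (1.75) and VIM (1.35), and in the NK library for 9, such as ITGAL (−1.79) and ITGB2 (−1.47). The median was −0.05 (percentile 73.9) and 0.23 with TMM scaling.

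**Figure D2:**
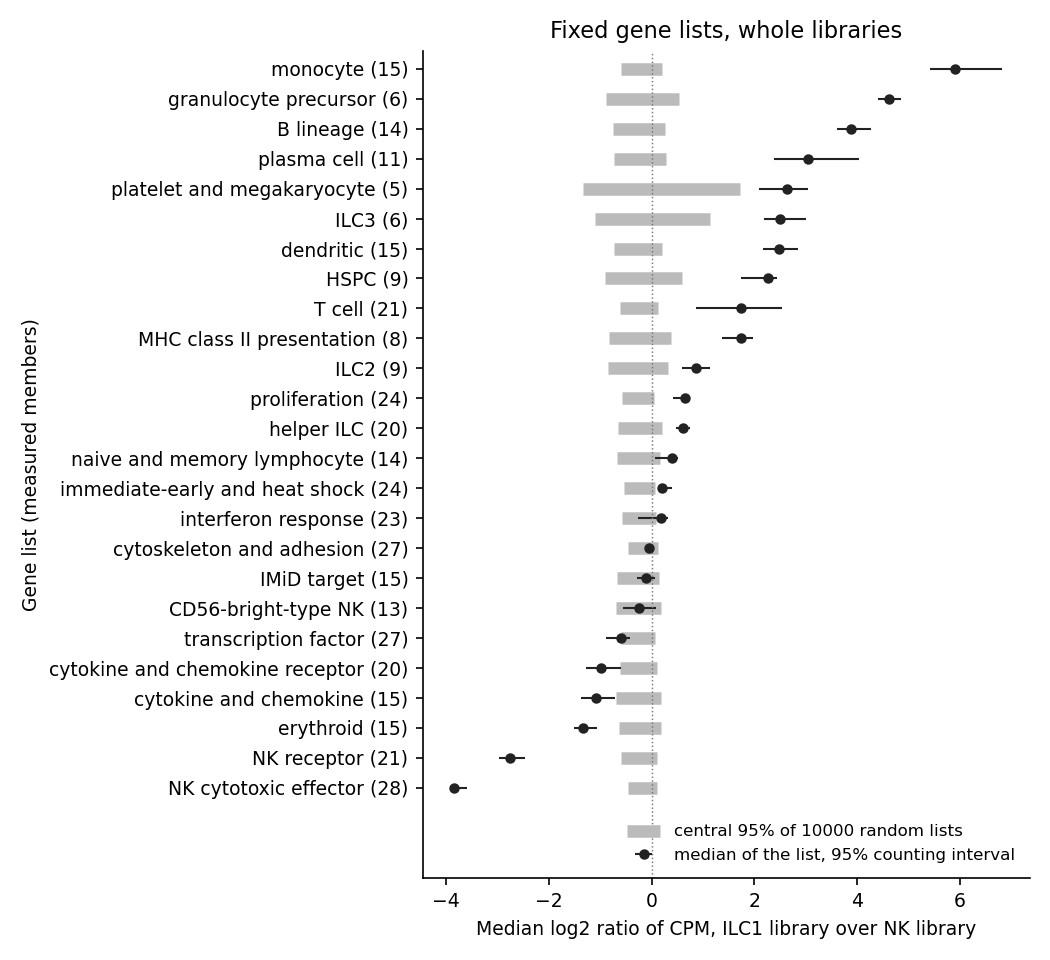
Median log2 ratio of CPM, ILC1 library over NK library, of each of the 25 fixed gene lists, with the number of measured members in brackets. Points are list medians with 95% counting intervals from 1000 resamples of the counts, and grey bars span the central 95% of 10000 random lists matched on expression; the monocyte list stands at 5.90 and the NK cytotoxic effector list at −3.83.

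The targets and partners of IMiDs were near equal between the libraries, apart from IKZF3 and IKZF2 toward the NK library and MYC and IRF4 toward the ILC1 library. Of 15 measured members of that list, 2 were higher on each side and 11 were neither, with a median of −0.11 (−0.29 to 0.06, percentile 77.1) that became 0.17 with TMM scaling. CRBN, the drug receptor (ENSG00000113851, chromosome 3, 3144628 to 3179727), stood at 74.6 CPM in the ILC1 library and 96.2 CPM in the NK library (log2 −0.37, −0.60 to −0.13). IKZF1, which encodes Ikaros (ENSG00000185811, chromosome 7, 50304068 to 50405101), stood at 77.5 and 106 CPM (log2 −0.46, −0.68 to −0.23). IKZF3, which encodes Aiolos (ENSG00000161405, chromosome 17, 39757715 to 39864188), stood at 22.1 and 83.7 CPM (log2 −1.92, −2.26 to −1.58). MYC, which acts downstream of these factors (ENSG00000136997, chromosome 8, 127735434 to 127741434), stood at 106 and 23.4 CPM (log2 2.18, 1.81 to 2.57). The casein kinase gene CSNK1A1 stood at a log2 ratio of −0.11, and IRF4 at 1.67. The whole-library values mix classes, and in monocyte-like cells IKZF3 stood at 0.626 CPM. After thinning, IKZF2 was detected in 12.8% of 39 NK-like cells of the ILC1 library (4.30 to 27.4%). In NK-like cells of the NK library it stood at 2.54% (1.51 to 3.98%), so NK-like cells did not show its whole-library direction. In the ILC1 library it was detected in 5.02% of T-like, 0 of 133 helper ILC-like and 0 of 371 monocyte-like cells. IRF4 was detected there in 9.23% of dendritic-like, 1.35% of monocyte-like, 0.913% of T-like and 0 of 133 helper ILC-like cells.

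The third comparison asked in what share of cells a gene was detected, with every cell thinned to 2000 UMIs, which kept 959 ILC1-library and 736 NK-library cells. Cytotoxic genes were found in most NK-library cells and in a minority of the ILC1 library. NKG7 was detected in 97.4% of NK-library cells (96.0 to 98.4%) and 22.4% of ILC1-library cells (19.8 to 25.2%), GNLY in 97.1 and 7.72%, and PRF1 in 90.8 and 11.8%. GZMB was detected in 85.6 and 8.24%, KLRD1 in 85.2 and 7.19%, KLRF1 in 79.9 and 4.48%, and the Fc receptor FCGR3A in 72.4 and 10.2%. The ILC1-library cells with FCGR3A were mostly in the unnamed cluster (51 cells) and the NK-like class (32 cells), and of those with GZMB 36 were NK-like and 25 dendritic-like. Monocyte-like cells of the ILC1 library, which should lack NKG7 and GNLY, showed them in 8.09 and 4.85% of cells at a median depth of 3228.5 UMIs before thinning, against 3244 UMIs in NK-like cells of the NK library. In the NK library itself NKG7 was detected in 4 of 10 erythroid-like and 4 of 17 dendritic-like cells, and GNLY in 5 of 10 and 5 of 17, at median depths of 4030 and 10716 UMIs. TBX21 was detected in 27.7% of NK-library cells (24.5 to 31.1%) and 2.19% of ILC1-library cells (1.36 to 3.33%), and EOMES in 8.02 and 1.36%; both were at 0 of 371 monocyte-like cells, an upper limit of 0.809%.

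IL7R was detected in 25.3% of ILC1-library cells (22.6 to 28.2%) and 1.49% of NK-library cells (0.748 to 2.66%), against 0.809% of monocyte-like cells. A CD3 subunit was detected in 23.7% (21.0 to 26.5%) and 5.30% (3.79 to 7.17%), TRAC in 21.4 and 4.89%, and CD27 in 6.57 and 2.99%, against 2.16, 1.89 and 0.270% of monocyte-like cells. Unthinned, IL7R was at 31.5 and 2.29%, the CD3 subunits at 28.99 and 6.74%, NKG7 at 29.2 and 99.3%, and TBX21 at 3.61 and 37.9%. CRBN was detected in 14.7% (12.5 to 17.1%) and 17.5% (14.8 to 20.5%) of cells, intervals that overlap, IKZF1 in 13.1 and 19.2%, and IKZF3 in 4.80 and 16.4%, against 8.89, 10.5 and 0.270% of monocyte-like cells.

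For KLRB1, which encodes CD161, the share was 42.3% in the ILC1 library and 81.9% in the NK library, but its CPM was the reverse, 1737 against 1360, so no order is read from the share. It was detected in 10.8% of monocyte-like cells. GZMK was at 13.1 and 9.24% and TCF7 at 8.45 and 8.70%, against 0.270 and 2.16% of monocyte-like cells for GZMK and TCF7. NCAM1, which encodes CD56, was at 0.417 and 7.88% with 0 of 371 monocyte-like cells, KIT at 0.521% and 0 of 736 cells (up to 0.408%), and IFNG at 0.104 and 0.679%, so KIT and IFNG were near the limit of detection at this depth.

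Comparisons of cell classes with each other were chosen after the data were examined, and they leave out marker genes that named the classes except where NK-like cells of the 2 libraries are compared. Clustering also separates genes that vary together with those markers, such as other effector genes. It therefore favours the contrasts between different classes, and these ratios describe the clusters. Helper ILC-like cells of the ILC1 library (150 cells) had no TBX21 UMI and lower levels of cytotoxic genes than NK-like cells of the NK library (800 cells). TBX21 had 0 against 433 UMIs, RUNX3 a log2 ratio of −3.66 (−4.98 to −2.60), ZEB2 −2.97 (−3.93 to −2.15) and HOPX −2.22, and MAF was higher at 2.51 (1.90 to 3.12). All 9 measured NK cytotoxic effector genes were lower, such as the granzyme GZMA (−7.34, −8.79 to −6.22) and CD247 (−3.47), and 7 of 10 NK receptor genes were lower, with KLRB1 (2.01) and KLRG1 (0.85) higher. IL7R (5.90, 5.35 to 6.50), LTB (4.43), TNFSF10 (2.43) and FLT3LG (1.84) were higher, and CCL5 (−7.72) was lower. Of 6 IMiD target genes, CRBN (0.60, 0.23 to 0.95) and MYC (4.35, 3.55 to 5.23) were higher, IKZF3 was lower (−1.63, −2.43 to −0.92), and IKZF1 (−0.05), CSNK1A1 and RBX1 (−0.22) were neither.

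T-like cells of the ILC1 library (267 cells, without the 3 immunoglobulin-rich cells) were also lower than NK-like cells of the NK library in all 9 measured effector genes, though less far for GZMA (−1.22, −1.34 to −1.10), and in TBX21 (−2.75), RUNX3 (−1.81) and ZEB2 (−5.18). They were higher in MYC (4.47, 3.71 to 5.32), IL7R (5.98), LTB (3.87), KLRB1 (1.70), RORA (0.91), TCF7 (1.06) and the chemokine receptors CXCR6 (3.33) and CCR6 (61 against 3 UMIs, 5.89, 4.28 to 8.21). Of the IMiD target genes IKZF1 was lower (−0.84, −1.28 to −0.41), and CRBN (−0.16) and IKZF3 (−0.57) were neither. Directly against T-like cells, helper ILC-like cells were higher in the integrin chain ITGB1 (2.67), TNFSF10 (2.13), IKZF1 (0.78) and CRBN (0.75, 0.30 to 1.21), and lower in IKZF3 (−1.06), CD2 (−5.20), GZMA (−6.12) and CCL5 (−7.19).

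Most effector and receptor genes were near equal in NK-like cells of the 2 libraries, but some of these genes also named the class, so the selection of the cells favours this. Of 25 effector genes 22 were neither higher nor lower, with GZMK (0.93), S1PR5 (0.68) and GZMH (0.65) higher in the ILC1 library. The share of cells with GZMK was not higher there, at 5.13% of 39 thinned NK-like cells against 9.45% of 709 in the NK library. T-like cells of the ILC1 library carried GZMK in 54.8%. No difference between NK cells is therefore read from the GZMK ratio. All 17 NK receptor genes and all 6 IMiD target genes were neither higher nor lower. Of 8 proliferation genes, TYMS (2.73, 1.25 to 4.01), TUBA1B (1.68), PCNA (1.15) and STMN1 (0.95) were higher in the ILC1 library's NK-like cells. So were 3 of 7 helper ILC genes, LST1 (1.70, 0.41 to 2.79), LTB (0.83) and ID2 (0.72), and 2 of 5 MHC class II presentation genes, HLA-DRA (1.27) and CTSS (0.67). Monocytes also express LST1, HLA-DRA and CTSS, and the monocyte gene S100A8 stood at 409 CPM in these cells and 1.19 CPM in NK-like cells of the NK library, so these 3 ratios are not read as a difference between NK cells. These 42 cells held 127221 UMIs against 2525991, and 37 and 5 of them lay in the 2 NK-like clusters that held 695 and 105 cells of the NK library, so small differences were not detectable at this depth.

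**Figure D3:**
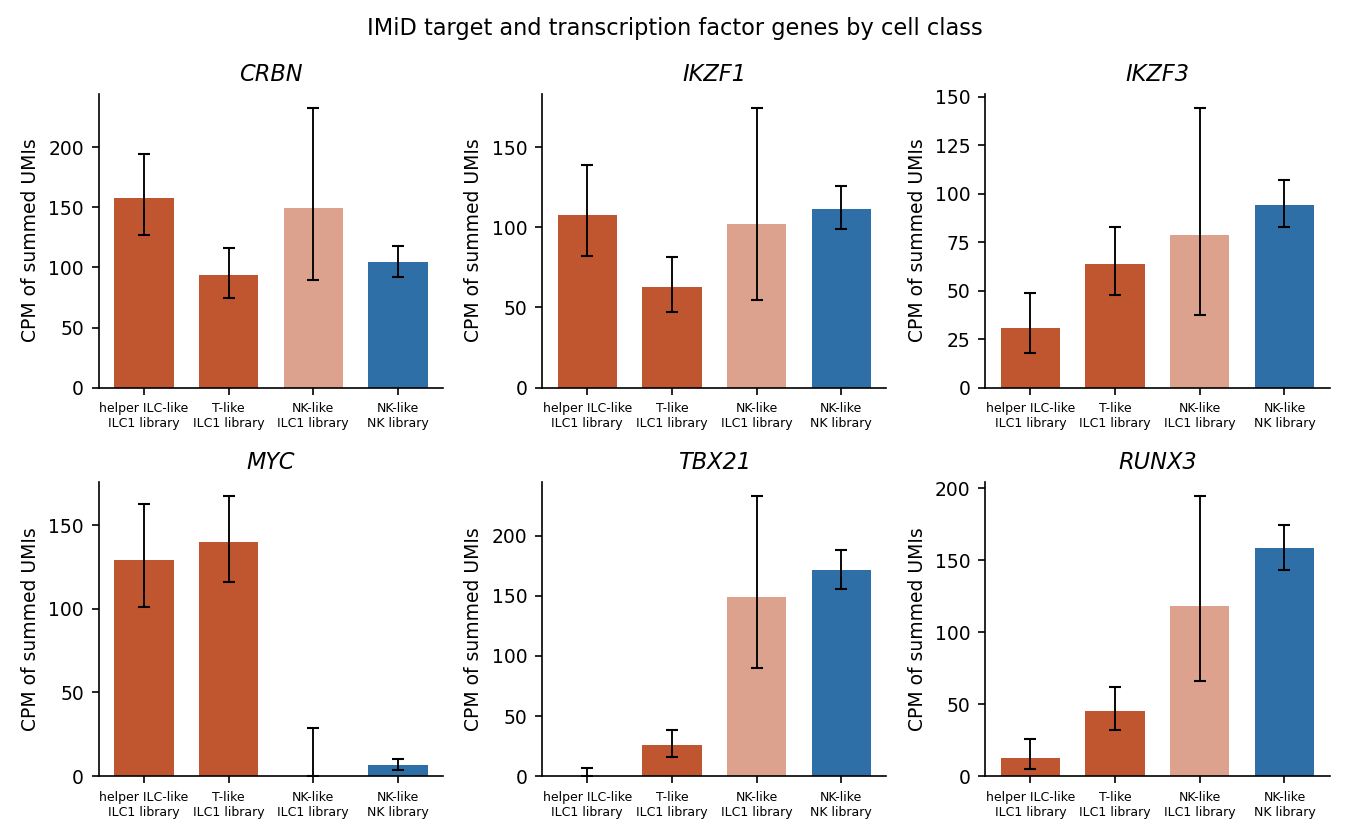
CPM of CRBN, IKZF1, IKZF3, MYC, TBX21 and RUNX3 in helper ILC-like (150), T-like (267) and NK-like (42) cells of the ILC1 library and in NK-like cells (800) of the NK library. Bars are the CPM of summed UMI counts with exact 95% Poisson intervals; TBX21 has 0 UMIs in helper ILC-like cells, and MYC has 0 UMIs in NK-like cells of the ILC1 library.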

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

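The tests here on NK-like cells only, on NK-like, T-like and helper ILC-like cells only, without the immunoglobulin-rich cells, and with naming without the 25% minimum were chosen after the results were seen. Of 30 alternative gene counts 18 stayed within 1.5 times the reported one; of 324 list medians 194 stayed within their counting interval, 110 moved and 20 reversed; of 1458 named-gene ratios 827 stayed, 619 moved and 12 reversed; of 184 shares with a UMI 110 stayed and 74 moved; and of 144 class shares 132 stayed and 12 moved. Doublet removal left all 25 list medians and all 16 class shares within their intervals. No paired analysis was possible because each population is 1 library. Depth limits the NK-like comparison: the 3-count floor of its 127221 ILC1-library UMIs lies above 20 CPM, and a gene at the floor in both libraries takes a log2 ratio of 4.31 there, which lifts the medians of lists with low members. That value therefore holds no monocyte signal for the median log2 ratio of the monocyte list. Where no reason is given, the cause was not tested.

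The count of genes at least 2-fold higher in the ILC1 library (494) was 759 with totals without ribosomal protein and mitochondrial genes, 770 at 10 CPM, 748 at 1.5-fold, 236 at 50 CPM, 277 at 4-fold, 326 without other-lineage clusters and 205 in NK-like, T-like and helper ILC-like cells only; the thresholds move a count by construction. The count of genes at least 2-fold higher in the NK library (873) was 1773 at 1.5-fold, 506 with TMM, 439 at 50 CPM, 220 at 4-fold and 122 in NK-like cells only, where 563 genes were higher in the ILC1 library and 3 UMIs reach 20 CPM in that library.

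Scalings and filters moved these medians: with TMM, NK cytotoxic effector −3.55, helper ILC 0.89 and IMiD target 0.17; without ribosomal protein and mitochondrial totals, helper ILC 0.75; with per-cell means, NK cytotoxic effector −3.57 and monocyte 7.19; with the stricter cell filter, helper ILC 0.99. With every member that had a UMI, helper ILC reversed to −0.17 and ILC2 to −0.41; with members at 20 CPM, helper ILC was 0.86, and ILC2 reversed to −0.51 and T cell to −0.76.

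The populations without other-lineage and without T-like clusters keep the unnamed cluster of 66 cells, which holds 365536 of the 1050044 ILC1-library UMIs in the smaller of them; LYZ was detected in 73.3% and S100A9 in 85.0% of its thinned cells, so monocyte genes stay in. Without other-lineage clusters, the median log2 ratio of the NK cytotoxic effector list was −2.89, with 1.65 for helper ILC and 2.74 for T cell, and proliferation (−0.48) and IRF8 (−1.32) reversed. Leaving out T-like clusters as well gave NK cytotoxic effector −2.63, helper ILC 0.98 and monocyte 6.86, and reversed T cell (−0.82), naive and memory lymphocyte (−0.20), proliferation (−0.39), plasma cell (−0.93), GZMK (−1.61), IRF8 (−0.75), CD3E (−1.03) and CD27 (−2.32).

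In NK-like, T-like and helper ILC-like cells only, the median log2 ratio of the NK cytotoxic effector list was −2.78, with 1.39 for helper ILC, 3.03 for T cell and 3.96 for monocyte, and proliferation (−0.43), MHC class II presentation (−0.58), dendritic (−0.64), RORA (0.61), IRF8 (−2.48), LILRB1 (−2.76), HLA-DPB1 (−0.67) and IRF7 (−0.81) reversed. In NK-like cells only, helper ILC was 0.77, T cell 0.12, IMiD target 0.51 and the median log2 ratio of the monocyte list 4.31, the ratio of the 2 floors. In these cells NK cytotoxic effector (0.0865), ILC2 (−0.23), naive and memory lymphocyte (−0.15), cytokine and chemokine (0.18), their receptors (0.34), transcription factor (0.0532), NK receptor (0.14), erythroid (0.61), CD44 (−0.90) and ID2 (0.72) reversed. With members at 50 CPM in the same cells, the medians were 0.14 for helper ILC, −0.00575 for T cell, 0.20 for IMiD target, 0.04 for cytokine and chemokine, 0.12 for their receptors and −0.15 for transcription factor, the last on the side of the reported value.

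Thinned to 500 UMIs, IL7R was detected in 10.3% of ILC1-library cells and a CD3 subunit in 12.7% and 1.203% of ILC1-library and NK-library cells; unthinned, IL7R stood at 31.5% and CD3 at 28.99% in the ILC1 library. With each library clustered alone, NK-like cells were 44.0% of the NK library, where the naming rule compares a cluster with mostly NK-like cells. Without the naming minimum as well, they were 53.9% of it and 9.52% of the ILC1 library. In the joint clustering all 16 class shares were the same without the minimum.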

Other observations

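All tests and class comparisons in this part were chosen after the results were seen. Within the NK library, the smaller NK-like cluster (105 cells) differed from the larger one (695 cells) in genes known from CD56-bright and CD56-dim NK cells. All 5 measured CD56-bright-type genes that had not named the class were higher in the smaller cluster (median log2 ratio 2.04), among them COTL1 (3.74, 3.25 to 4.26), the stem-like factor TCF7 (2.04, 1.51 to 2.56), CD44 (1.57) and IL7R (27 against 2 UMIs, 4.48 to 9.59). The chemokine receptor CXCR3 (2.52, 1.60 to 3.43) and AREG (1.87) were also higher, and so were 7 of 17 immediate-early genes, such as FOS (1.84) and DUSP2 (1.81). Of 10 effector genes 7 were lower, such as CX3CR1 (−2.14, −3.07 to −1.35) and S1PR5 (−1.37), with ZEB2 (−2.16) and 12 of 25 cytoskeleton and adhesion genes, such as LGALS1 (−2.50) and S100A4 (−1.45); none of 5 IMiD target genes differed by the 1.5-fold rule. Clustering itself separates such genes, so these ratios describe the clusters.

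A minority of T-like cells of the ILC1 library carried SLC4A10, a transporter gene known from mucosal-associated invariant T cells, or the chemokine receptor CXCR6, both chosen after their values were seen. After thinning, SLC4A10 was detected in 13.7% of 219 T-like cells (9.44 to 19.0%) and CXCR6 in 11.4% (7.53 to 16.4%). They were each detected in 0.270% of monocyte-like cells and in 0 of 133 helper ILC-like cells.

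Monocyte-like cells were the most frequent class in a library sorted for ILC1s, although such a sort would be meant to remove them. Free RNA in droplets of lymphoid cells and doublets with a lymphoid cell would both leave lymphoid markers in these cells. Both are argued against by 40 T, NK and helper ILC markers, which stood at 165 CPM in monocyte-like cells and 5807 CPM in lymphoid cells, or 2.85%; a first choice of which markers to leave out gave a lower value, also far below 25%. A sort gate that let other cells in and a wrong label cannot be told apart, since both put cells outside the lymphoid classes (59.3% here) and 1 library per sort gives nothing to separate them. Droplets with free RNA and no cell were not tested, and no biological explanation was tested.

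S100A8 was found at a low level in lymphoid cells of the ILC1 library and hardly at all in NK-like cells of the NK library (1.19 CPM). A candidate source is free RNA from the monocyte-like cells, which held 28066 CPM: T-like, NK-like, helper ILC-like and B-like cells stood at 430, 409, 427 and 424 CPM, a largest-to-smallest ratio of 1.05, as 1 shared source would give. Among the cells clustered as lymphoid, doublets with monocytes are argued against. Of 376 such cells with an S100A8 UMI, 0 (0%) reached 25% of the monocyte-like median of 71 UMIs. S100A8 was the most enriched gene of a monocyte-like cluster, so doublets with more S100A8 may have been placed there and were not counted. Low UMI shares of other monocyte genes in lymphoid cells of this library may have the same source, which was not tested. No biological explanation was tested.

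Helper ILC-like cells of the ILC1 library carried GATA3 (71.4% of 133 cells, 63.0 to 78.9%) and PTGDR2 (21.1%) at 2000 UMIs, against 0.809 and 0.270% of monocyte-like cells, and 0 of the 133 had a TBX21 UMI. PTGDR2 helped to name this cluster and both genes are among its 10 most enriched, so their shares restate how it was formed, and of the 3 ILC2 genes left over 1 was higher and 2 neither against NK-like cells of the NK library (median 0.29), and 1 higher, 1 lower and 1 neither against T-like cells (median −0.14). Few cells of this cluster had a CD3 subunit UMI, 3.01% against 94.1% of T-like cells, or 3.20% of that share. TRAC was detected in 18.0% of helper ILC-like cells, against 78.1% of T-like cells and 5.08% of NK-like cells of the NK library. TRDC was detected in 44.4, 5.48 and 56.4% of them, so it was not particular to T-like cells. The CD3 genes helped to name the T-like cluster and are among its 10 most enriched, so the clustering favours the CD3 contrast. By itself the CD3 contrast does not decide whether T cells lie in the helper ILC-like cluster. From the GATA3 share (71.4%), a sort gate that let cells of the ILC2 type in and a wrong label cannot be told apart. No biological explanation was tested, and the design names none.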
